A study of Mus musculus with 4 samples.

How the data were processed

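Trimethylation of histone H3 at lysine 36 (H3K36me3), a chromatin mark that is laid down over the bodies of transcribed genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq). Per the labels' protocols, myoblasts were isolated from skeletal muscle of FVB mice on postnatal day 4, kept in culture for 5 to 10 passages, and differentiated by growth factor withdrawal for 24 hours before harvest. Libraries were made from 10 ng of DNA. The series holds 4 samples, 1 H3K36me3 library and 1 input DNA library from wild-type cells, and the same from cells that carry a deletion of a muscle-specific enhancer of the H19/Igf2 locus. Processed files of the 2 H3K36me3 libraries were used. The 2 input libraries were not analysed here.

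Each of the 2 files is a list of islands, with a chromosome, a start, an end and an island score deposited by the authors. Per the submitters' processing notes, the tools were Bowtie 1.0.0, a short-read aligner, and SICER 1.1, a caller of broad enriched regions, with the mouse build mm9. The deposited file names give a window of 200 bp and a gap of 600 bp, and all island starts and lengths are multiples of the window. Whether the authors used the input libraries or removed duplicate reads to make these lists is not given in the sources used here. One list was deposited per library, so nothing was pooled. Island ends in the deposited lists are the last covered base counted from 0, and coordinates are printed here counted from 1.

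An island score in SICER is the sum, over windows with enough reads, of the negative natural log of the Poisson probability of the window's read count, with a ceiling of 1000 per window. It therefore grows with depth and with island length, so the deposited scores were not compared between lists, apart from the lowest scores of the lists and the limits of their score groups. Deposited scores were used within a list to rank, filter or describe islands, to solve depth and window counts as given next, and, as score per window, to set chromosomes of a list against each other. The files give no read totals, but the scores of islands that are 1 window long take only the values that whole read counts allow. From those (8 islands in the wild-type list and 14 in the mutant list, 6 distinct scores in each) the mean number of reads per window was solved as 2.82 in the wild-type library and 3.11 in the mutant library, with residuals of at most 3.4e-08 in score units. The mutant library was thus 1.10 times as deep by this measure. The total number of reads was not computed, since the effective genome size used by the authors is not given. Scores of 28 of 29 and 149 of 150 islands of 2 windows then split into 2 whole counts, of which the smallest was 5 reads in the wild-type list and 6 reads in the mutant list.

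All comparisons were made on arrays of 200 bp windows with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. An island had a counterpart when at least 1 bp of it was covered in the other list. The shared length was expressed as a Jaccard index, the covered length common to both lists as a percentage of the length covered in either. As a description of chance, islands of a list were placed at random within their own chromosomes 100 times. Cover was also summed in 100 kb bins, where a bin was called covered at 50% or more and uncovered below 1%. Each chromosome was further searched for the single position that best divided the log2 ratio of mutant to wild-type cover in 500 kb bins, with at least 20 bins on each side and 1% of a bin added to both values. The comparisons of island number, covered length, overlap, counterparts, score ranks, chromosomes and 100 kb bins, the rule for named regions and the other alternatives were fixed before the data were examined. Chosen after seeing the data were the depth solved from scores, the counts of islands of 10 or 20 kb and more, the split search, the singling out of chromosome 14, the view of distal chromosome 7 and the settings without chromosomes 14 and 15. The plan named bedtools for overlaps, and the window arrays were used in its place.

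With 1 library per genotype there is no replicate spread, so no test of genotype was possible and no p-value is given. Intervals are exact binomial 95% intervals (Clopper-Pearson) and cover counting error only. The computations were tested on simulated data. Depths were solved from the scores of simulated read counts. The tests of removed islands, boundaries and even thinning altered the wild-type list. All 20 simulated depths were recovered within 0.0001 reads per window, all 200 removed islands were found, and 18 of 19 simulated boundaries were found within 3 Mb. When islands of the 19 autosomes were thinned evenly, with no boundary, the largest split statistic was 3.76.

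Regions were named by a rule: the 5 islands with the highest score in each list, the 5 longest, the 5 longest with no overlap in the other list, and the 5 bins with the largest difference in each direction. Planned comparisons of gene bodies, of fixed gene lists (among them muscle genes, imprinted genes and markers of other cell types) and of islands over Igf2, H19 and Nctc1 were not run, because the gene table used here is on GRCm38 and the islands are on mm9. On 3 of 20 chromosomes islands lay over 1 Mb past the last gene of that table. It was used only for gene names and for which genes neighbour each other. Alternative settings were a stricter list (the upper 50% by score), lists of equal covered length, islands of at least 2 kb, islands within 2 kb joined, an overlap of 50% of the island or 50% reciprocal, and 20 kb bins.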

Results

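H3K36me3 was profiled in wild-type myocytes and in myocytes that carry a deletion of a muscle-specific enhancer of the H19/Igf2 locus, with 1 ChIP-seq library per genotype. The question addressed by the design is how the mark is distributed across the genome with and without this enhancer. H19 is an imprinted long noncoding RNA gene and Igf2 encodes insulin-like growth factor 2. The wild-type list held 58326 islands that covered 308.1 Mb, and the mutant list held 69798 islands that covered 297.8 Mb. As solved from the scores, the depth was 2.82 reads per 200 bp window in the wild-type library and 3.11 in the mutant library. Values below are for these 2 libraries, which have no replicate check.

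Islands were 1.20 times as many in the mutant list and shorter on average, but among islands of at least 2 kb the ratio was 1.00469. The mean island length was 5282 bp in the wild type and 4267 bp in the mutant, and the medians were 3800 and 3000 bp. In the full lists the covered length in the mutant was 0.967 times that in the wild type. It was 1.00268 times in the upper 50% of each list by score, and 0.916 to 0.993 times in the other settings. The upper 50% was not an equal cut. It held 1.20 times as many mutant as wild-type islands, with lowest scores of 51.9 and 63.3. The direction thus depended on the setting. Islands of 20 kb or more numbered 1105 in the wild type and 922 in the mutant. The smallest read count of a window inside a 2-window island was 5 in the wild-type list and 6 in the mutant list, and the lowest island scores were 30.3 and 22.6.

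By an overlap of at least 1 bp most islands were found in both genotypes, and nearly all of those with the highest scores; at 50% reciprocal overlap the shares were 55.4% of wild-type and 46.3% of mutant islands. The lists shared 222.4 Mb, a Jaccard index of 58.0%, against a mean of 6.70% (range 6.55% to 6.91%) for randomly placed islands. At 1 bp, 82.0% (95% interval 81.7% to 82.4%) of wild-type islands had a counterpart in the mutant, and 74.3% (74.0% to 74.6%) of mutant islands had one in the wild type. Random placement gave 24.8% and 21.3%. It ignored where transcribed genes lie, so overlap above it does not measure how alike the 2 genotypes are. When islands shorter than 2 kb were removed from both lists, the order turned, with 75.03% and 78.3%. There, an island that overlapped only shorter islands of the other list counted as having no counterpart. With each list cut into 10 equal groups by score, the shares were 99.5% and 99.5% in the highest group, and in the lowest 55.2% of wild-type and 41.5% of mutant islands. Higher groups also held longer islands, with medians from 2200 to 13600 bp in the wild type and from 1600 to 12000 bp in the mutant. Random placement was not split by score group, so part of the rise may come from length. Islands without a counterpart had a median length of 3200 bp in the wild type and 2000 bp in the mutant, against 4200 and 3400 bp for those with one. Only 52 wild-type and 31 mutant islands without a counterpart reached 10 kb.

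**Figure D1:**
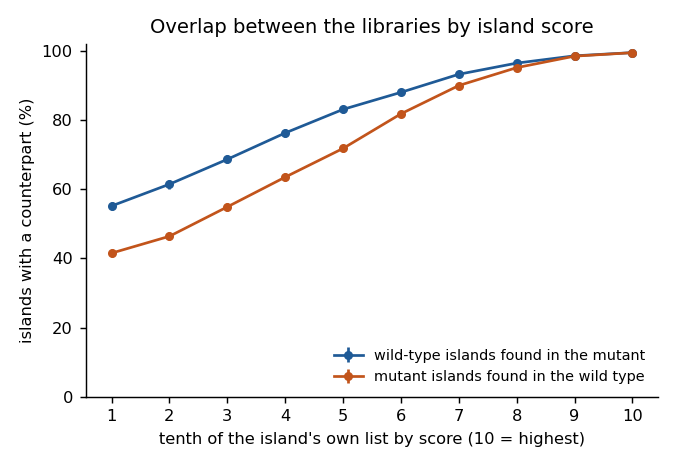
Percentage of islands with at least 1 bp covered in the other library (y axis) by score group of the island's own list (x axis, 10 equal groups), for wild-type islands and mutant islands. Points are shares and bars are exact 95% binomial intervals for counting error. The shares climb from 55.2% and 41.5% in the lowest group to 99.5% in the highest group of both lists. Islands in higher groups are also longer.

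The 4 islands with the highest scores lay at the same places in both libraries. Whether input DNA shows an excess of reads at these places, as repeated sequence can, was not analysed here, so their scores and their agreement are not a measure of H3K36me3. The top island spanned chromosome 9 from 2999801 to 3038600 (mm9) in the wild type and ended at 3038400 in the mutant, with deposited scores of 172768 and 179252. It was followed in both lists by islands on chromosome 11 (3024801 to 3100200 in the wild type), chromosome 2 (98502201 to 98507600) and chromosome 17 (39979801 to 39985800). On average each window of the chromosome 9 island scored 891 in the wild type and 929 in the mutant, where the median island score per window on any one autosome lay between 3.44 and 4.42. These averages lie near the ceiling of 1000 per window and do not measure a difference between the libraries. The fifth was on chromosome 6 (84043801 to 84164400) in the wild type, which at 120.6 kb was also the longest wild-type island and was 85.6% covered in the mutant. In the mutant the fifth was on chromosome 8 (19987001 to 20026200), and 98.0% of it was covered in the wild type. The other longest wild-type islands lay on chromosome 15 (27738401 to 27848600, 110.2 kb), chromosome 6 (91634401 to 91715600, 81.2 kb), the chromosome 11 island just given (75.4 kb) and chromosome 2 (76542201 to 76617600, 75.4 kb). The longest mutant islands were on chromosome 15 (76902601 to 76986800, 84.2 kb), chromosome 11 (3025201 to 3100200, 75 kb), chromosome 6 (71783001 to 71852600, 69.6 kb, and 65802401 to 65862800, 60.4 kb) and chromosome 2 (76539001 to 76598200, 59.2 kb). Between 85.6% and 100% of each of these was covered in the other library.

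Chromosome 6 was the most covered chromosome apart from the mitochondrial genome in both libraries, and chromosome X was the least covered apart from the mutant's chromosome Y. Islands covered 18.1% of chromosome 6 in the wild type and 17.7% in the mutant, where the other autosomes lay between 8.65% and 15.3% in the wild type. The small difference between the libraries on chromosome 6 turned in each alternative setting, and no direction was read from it. The upper 50% kept more mutant than wild-type islands, and equal covered length removed wild-type islands alone. With islands joined the values were 19.17% and 19.19%. Chromosome X was covered to 0.934% by 404 islands in the wild type and to 0.842% by 520 islands in the mutant, and to 0.339% and 0.232% in the upper 50% of the lists by score. On chromosome Y, 24 islands covered 101.8 kb in the wild type and 6 islands covered 10.8 kb in the mutant, a ratio of 0.106. The cause of this difference was not tested.

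Among the autosomes, chromosome 14 stood apart between the genotypes. It held 10.8 Mb of islands in the wild type and 7.28 Mb in the mutant, a ratio of 0.672, whereas the other 18 autosomes had ratios between 0.875 (chromosome 4) and 1.06 (chromosome 15). It was also the autosome with fewer islands in the mutant, 1928 against 2234, where the others had 1.12 to 1.29 times as many as the wild type.

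**Figure D2:**
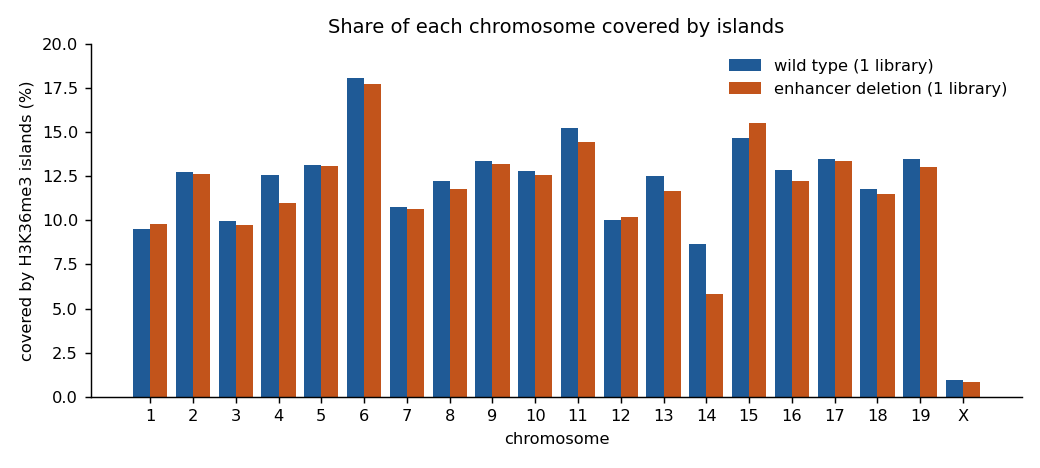
Percentage of each chromosome covered by H3K36me3 islands (y axis) for chromosomes 1 to 19 and X (x axis), with 1 bar per library and no error bars because there is 1 library per genotype. Chromosome 6 is the highest in both (18.1% and 17.7%), chromosome X is below 1% in both, and chromosome 14 is lower in the mutant (5.82%) than in the wild type (8.65%).

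The difference on chromosome 14 lay in its distal part. The position that best divided the chromosome, searched for after the data were seen, was at 70.5 Mb. Up to there the mutant covered 0.928 times the wild-type length, and past it 0.170 times, with 3.65 Mb of islands in the wild type and 0.621 Mb in the mutant. Wild-type cover was highest in the 2 Mb bins from 70 to 80 Mb, at 13.7% to 35.6% against 2.48% to 7.46% in the mutant. Each bin past 80 Mb was covered to at most 12.2% in the wild type, so the ratio rests largely on the part before 80 Mb. Cover was lower in the mutant in each of the bins past 80 Mb as well, at most 4.6%. Chromosome 15 was divided at 61.5 Mb, with ratios of 0.738 before and 1.35 past the boundary. The split statistics of chromosomes 15 and 14 were 9.97 and 9.46 in absolute size, against at most 3.70 on any other chromosome (chromosome 12).

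**Figure D3:**
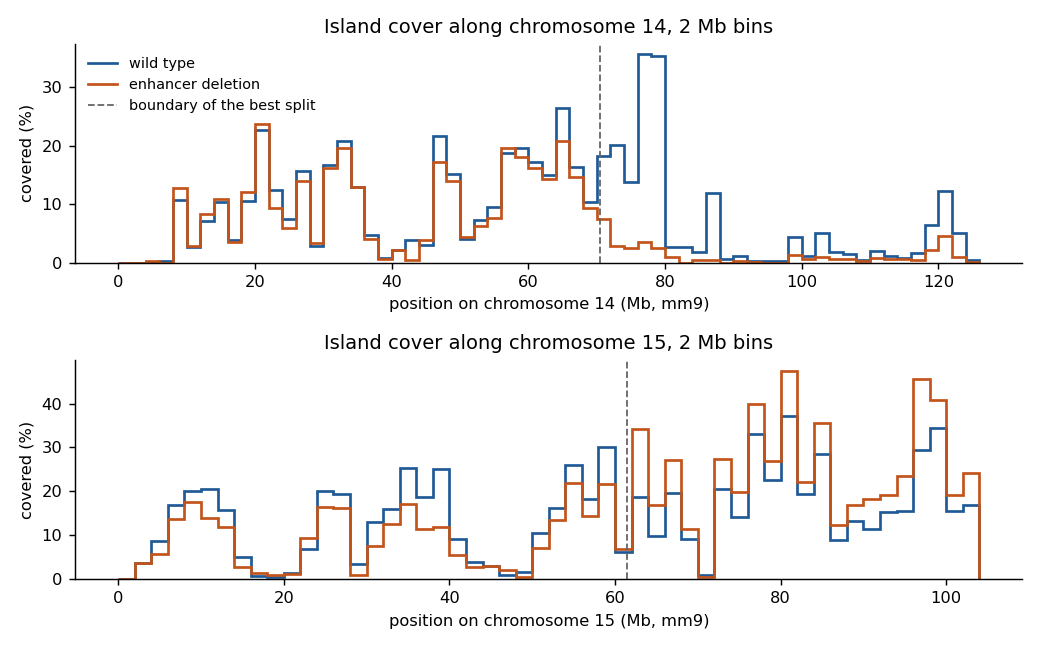
Percentage covered by H3K36me3 islands in 2 Mb bins (y axis) along chromosomes 14 and 15 (x axis, Mb on mm9) in the wild-type and mutant libraries. Dashed lines mark the best-dividing positions at 70.5 and 61.5 Mb. Past 70.5 Mb on chromosome 14 the mutant covers 0.170 times the wild-type length, and on chromosome 15 the ratio is 0.738 before and 1.35 past 61.5 Mb.

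In 100 kb bins the 2 libraries were similar over most of the genome. Across 15245 bins with an island in either list, the Spearman correlation of cover was 0.87 and the Pearson correlation 0.92; bins are not independent replicates. The cover differed by less than 10 percentage points in 85.1% of bins. Of 1522 bins covered in the wild type, 3 were uncovered in the mutant, and all 3 lay past the boundary on chromosome 14, starting at 73000001, 77100001 and 79000001. Of 1568 bins covered in the mutant, 2 were uncovered in the wild type. These were adjacent on chromosome 5, from 113100001 to 113300000, with 0% in the wild type and 79.0% and 87.2% in the mutant. The counts depended on the settings: they were 141 and 98 with 20 kb bins, 1 and 3 in the upper 50% by score and 0 and 2 without chromosomes 14 and 15.

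The largest differences in favour of the mutant came after those 2 bins on chromosome 10 (86300001 to 86400000, 4.2% in the wild type and 79.6% in the mutant), chromosome 15 (97100001 to 97200000, 19.8% and 84.6%) and chromosome 13 (60700001 to 60800000, 6.2% and 62.4%). The chromosome 15 bin lay past the boundary, where cover was higher in the mutant as a whole. In favour of the wild type they were on chromosome 11 (58800001 to 58900000, 91.2% in the wild type and 27.2% in the mutant), chromosome 4 (95400001 to 95500000, 72.0% and 13.0%) and past the boundary on chromosome 14. The chromosome 14 bins started at 79400001 (67.8% and 4.2%), 73600001 (71.0% and 10.8%) and 79800001 (62.4% and 3.8%).

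Some of the longest islands seen in 1 library alone lay in the bins just named. Of the 5 longest mutant islands with no overlap in the wild type, 4 lay on chromosome 5 between 113126401 and 113277200, the longest of 31.4 kb, and the other on chromosome 10 (86442201 to 86463200, 21 kb). The 5 longest wild-type islands with no overlap in the mutant were on different chromosomes. They were on chromosome 18 (61960401 to 61984800, 24.4 kb), chromosome 12 (101223201 to 101239600, 16.4 kb), chromosome 1 (85098401 to 85113400, 15 kb), chromosome 14 (79425801 to 79440800, 15 kb, within a bin named above) and chromosome 17 (46664601 to 46679400, 14.8 kb).

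The targeted locus lies on chromosome 7, where the GRCm38 gene table orders Tnnt3 (a fast skeletal muscle troponin T), Mrpl23, Nctc1, H19, Igf2 and Ins2 as neighbours with other noncoding genes among them. Which islands lie over these genes on mm9 was not analysed here. The last 5 Mb of the chromosome, 147500001 to 152500000, was covered to 17.3% by 140 islands in the wild type and to 16.0% by 153 islands in the mutant, and 25 and 29 of these had no counterpart. Among its 250 kb bins the largest difference in favour of the wild type was 20.4% against 9.52%, at 152000001 to 152250000, and in favour of the mutant 3.12% against 12.1%, at 151750001 to 152000000. The bin from 149750001 to 150000000, singled out after its values were seen, held 22.8 kb of islands in the wild type and 5.6 kb in the mutant. There, wild-type islands at 149752001 to 149754600, 149787201 to 149792400 and 149849201 to 149861000 (11.8 kb) had no counterpart in the mutant, and neither had the mutant island at 149964601 to 149967400 in the wild type. This bin was not alone. The bin from 149250001 to 149500000 held 13.4 kb in the wild type and 3.2 kb in the mutant. In the other direction, 151750001 to 152000000 held 7.8 kb and 30.2 kb. The bin with the largest difference in favour of the wild type held 8 wild-type islands with no counterpart, between 152089601 and 152249400, and 3 such mutant islands. The bin with the largest difference in favour of the mutant held 6 mutant islands with no counterpart, between 151776601 and 151875400.

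**Figure D4:**
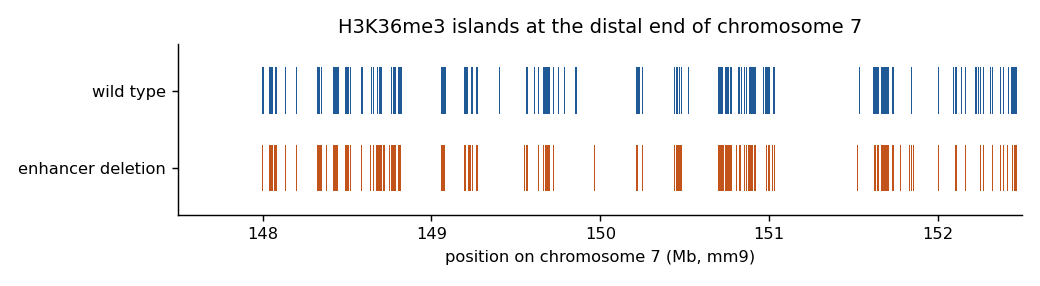
H3K36me3 islands in the last 5 Mb of chromosome 7 (x axis, Mb on mm9) in the wild-type library (upper row) and the mutant library (lower row); each block is 1 island drawn to scale. The wild type holds 140 islands and the mutant 153, and 25 and 29 of these have no counterpart in the other library.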

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

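The settings without chromosomes 14 and 15 came after the result was seen, and chromosome 14 was singled out then from a comparison planned for every chromosome. The order of the libraries changed in 4 quantities (covered length, counterpart shares, 100 kb bins covered in 1 library alone and chromosome 6 cover), and the cause was not tested. Some settings treated the lists unequally, which can turn an order by itself. The upper 50% kept 1.20 times as many mutant as wild-type islands. Equal covered length removed 4428 wild-type islands and no mutant islands. The mutant to wild-type ratio of covered length was 0.967 in the full lists and 1.00268 in the upper 50% of each list by score, and it was 0.916 with islands of at least 2 kb, 0.993 with islands within 2 kb joined and 0.973 without chromosomes 14 and 15. The ratio of island numbers was 1.00 (1.00469) with islands of at least 2 kb, 1.10023 with islands joined and 1.21 without chromosomes 14 and 15. The Jaccard index was 57.2% (upper 50%), 57.8% (equal covered length), 56.5% (at least 2 kb), 60.8% (joined) and 58.6% (without chromosomes 14 and 15). In the same order of settings, wild-type islands had a counterpart in 82.4%, 84.3%, 75.03%, 80.4% and 83.1% of cases. Mutant islands had one in 71.4% (equal covered length), 78.3% (at least 2 kb, above the wild type) and 73.9% (joined). In the setting of at least 2 kb, shorter islands were first removed from both lists, so overlap with a shorter island did not count. Asking for overlap of 50% of the island gave 73.2% and 69.9%, and 50% reciprocal overlap 55.4% and 46.3%, for wild-type and mutant islands. The chromosome 14 ratio stayed below that of the other autosomes as deposited, at 0.681, 0.702 and 0.693 (upper 50%, equal covered length, joined). The Spearman correlation was 0.735 in 20 kb bins, 0.820 in the upper 50% and 0.887 without chromosomes 14 and 15. With 20 kb bins, 141 bins were covered in the wild type and uncovered in the mutant, and 98 the other way. Bins of 100 kb covered in the wild type alone numbered 1 in the upper 50% and 0 without chromosomes 14 and 15, since all 3 lay on chromosome 14; those in the mutant alone numbered 3 and 2, so the upper 50% and the removal of these chromosomes turned 3 against 2 into 1 against 3 and 0 against 2, with 2 against 2 at equal covered length and 3 against 3 with islands joined. Chromosome 6 cover was 14.2% in the wild type and 14.4% in the mutant in the upper 50%, 17.6% and 17.7% at equal covered length, and 19.17% and 19.19% with islands joined. Chromosome X stayed below 1% throughout and was lowest in the upper 50% (0.339% and 0.232%). Comparisons of genes, gene lists and the Igf2/H19 locus were not run under any setting. With 1 library per genotype, no replicate could be left out. What depth limits was not tested: 55.2% and 41.5% of the lowest of 10 groups by score had a counterpart, and those islands were also short (medians of 2200 and 1600 bp).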

Other observations

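The tests in this part were chosen after the result was seen, except 2 whose values had not been looked at: the cover of the upper 1 of 3 score groups of wild-type islands on distal chromosome 14, and chromosome 6 without its highest-scoring islands. No biological explanation by genotype was tested, since genotype and library cannot be separated with 1 library of each.

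Cover on chromosome 4 was lower in the mutant, with 17.1 Mb against 19.6 Mb. Its best split, at 71.0 Mb, had a statistic of 3.09, below the 3.76 of evenly thinned islands.

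Distal chromosome 14 (70500001 to 125087600, mm9) held 793 islands in the wild type and 221 in the mutant, and chromosome 15 shifted in opposite directions on the 2 sides of 61.5 Mb. Library-wide depth or calling settings are argued against, because the lowest ratio among the other 18 autosomes was 0.875 and chromosome 15 had 0.738 and 1.35 (1.34723) on its 2 sides, where sides found by the same search on the remaining autosomes ran from 0.770 to 1.09838, so the lower value is only just outside. The split statistics of 9.46 and 9.97 were larger than on any other chromosome. They do not decide against separate changes at single transcription units, because this test was chosen after the statistics were seen. The same search gave at most 3.70 on the other chromosomes. It gave 3.76 with evenly thinned islands, but these lost single islands independently and gained none, so they do not model changes at units. The split statistic also uses the bins that set the boundaries, and neighbouring units that shift together were not tested. The shares of bins with less cover past the boundary on chromosome 14 (94.1%) and no less on chromosome 15 (92.4%), the test tried first, were set aside because the same bins set the boundaries, and the search gave up to 90% and 63.8% elsewhere. Fewer copies of distal chromosome 14 in the mutant line is a candidate explanation that stays undecided: the mutant covered 20.4% of the length of the highest-scoring of 3 groups of wild-type islands there, against 84.1% elsewhere, but its total cover of the segment allowed at most 34.7%, already below the limit of 42.0%. A lower level of the mark over the whole segment, extra copies in the wild-type line and a gain of distal chromosome 15 in the mutant stay open as well: the median island score per window past the boundary on chromosome 14 was 3.46 in the wild type and 3.02 in the mutant, and on chromosome 15 it was 3.73 before and 3.72 past the boundary in the wild type and 3.96 and 4.30 in the mutant, against 3.49 to 3.75 and 3.86 to 4.04 on whole autosomes other than 6, 14 and 15, but no spread was available and input reads were not analysed here.

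The mutant list had more and shorter islands, with no excess among islands of at least 2 kb (ratio 1.00469). More marked sequence found by deeper sequencing cannot be told apart from other explanations. The covered-length ratio was 0.967 in the full lists and 0.916 to 0.993 in other settings. It was 1.00268 in the upper 50% by score, which held 1.20 times as many mutant as wild-type islands. The lists also had unequal lowest scores, so the ratio cannot decide this. A candidate explanation is a different read minimum per window: the smallest window count in 2-window islands was 6 in the mutant and 5 in the wild type. At the solved depths the Poisson probability of 5 or more reads is 0.155 in the wild type and 0.203 in the mutant, so a tail limit of 0.2 gives these minimums. The lowest island scores differed as well, at 30.3 in the wild-type list and 22.6 in the mutant list. The lowest 2 of 10 score groups of the mutant list, with 6980 islands each, lay wholly below the wild-type minimum. Of these, 41.5% and 46.4% had a counterpart, so they also lower the mutant share of 74.3%. How far the read minimum or the unequal lowest scores changed the number and length of islands was not measured.

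Chromosome 6 was the most covered autosome in both libraries. A few strongly marked regions are argued against, since without the highest-scoring 1 in 10 islands of each chromosome it was still the most covered, with 12.3% against at most 10.7% on another autosome in the wild type, and 11.5% against 10.0% in the mutant. More copies of chromosome 6 in both lines is a candidate explanation: the median island score per window was 4.06 on chromosome 6 in the wild type, above the 3.44 to 3.75 of the other autosomes, and 4.42 in the mutant, above 3.70 to 4.12. A higher content of transcribed genes stays open as well, since no gene annotation on mm9 was used. Whether gene content raises the score per window was not tested.

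In each list, 4 of the 5 highest-scoring islands coincide with those of the other. Whether the input libraries show the same excess at these places was not analysed here.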
